A study of Helianthus annuus with 9 samples.

How the data were processed

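The series holds 9 small RNA libraries from developing seeds of the sunflower line L-1-OL-1, 3 at each of 7, 22 and 37 days. Per the labels, total RNA was extracted with a CTAB and pBIOZOL protocol, a gel band of 18 to 30 nt was taken, 3′ adapters annealed to unique molecular identifiers were ligated, and the libraries were sequenced on a BGISEQ-500. The labels name Bowtie2 without a version or a role. The genome build, the counting tool, any filter and whether reads were collapsed by their molecular identifiers are not given in the sources used here.

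The deposited table gives, for each library, a whole-number column that per the file headers is a count of reads per small RNA entry, with no normalization by the authors. A further column per library is headed TPM. Its values equal the counts for the genome totals, so they sum to nearly as much as the reads do. They lie at or below the count (median ratio 1 under 100 reads, with 0.667 as the lowest there, and 0.872 for the most abundant known miRNAs). The column was therefore treated as a deposited score of unstated meaning and used only as an alternative. Genome coordinates of the predicted miRNA precursors and guide sequences of the predicted siRNAs, which are other values per the file headers, were used as deposited for position, identity and length. They stand on named RefSeq sequences of a build that is not given in the sources used here, so no gene annotation was joined to them.

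Entries were classed by their names and sequence lists as known miRNA, hairpin of a known miRNA, predicted miRNA, siRNA (21, 22 or 24 nt by guide length) and structural RNA (ribosomal, transfer, small nuclear and small nucleolar RNA and other Rfam models). The table has 8476 entries, of which 3 are totals for exons, introns and intergenic sequence, which left 8473 small RNA entries. Library size was the sum of these entries, 2208822 to 4050364 reads, of 31011803 to 34397084 reads in all. Predicted miRNAs and siRNAs are listed only from 10 reads. A 0 was therefore taken to allow up to 9 reads in a library. That is an assumption, since any filter is not given and a 0 could have another meaning. Under it, folds against a group at 0 are lower bounds against 9 reads per library. These bounds set only the zeros to 9 reads. They take the mean of the other group as it is and cover neither counting error nor the spread between libraries. The entries of 345 siRNAs share a guide sequence with another entry. The 1 listed predicted miRNA and the 3 listed siRNAs whose sequence lines are empty were counted but are not named.

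Counts were tested in edgeR 4.0.16 under R 4.3.3 with TMM factors, filterByExpr by time point, and the quasi-likelihood F test in one fit of all 9 libraries with a mean per time point. Adjusted p-values are Benjamini-Hochberg over the 7294 small RNAs tested, with a threshold of 0.05. Conserved families were tested by the sum of their mature and hairpin entries, with the factors of the full table, and adjusted over the families alone. A family came from the miRNA number in the name. Matching by sequence added 0 entries, so other matching rules, with exact sequence or 1 mismatch, changed nothing and have no values of their own. Lists were compared with all other small RNAs by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, at least 3 tested members). The lists were phase change (miR156, miR172), auxin (miR160, miR167, miR390, miR393), developmental factors (miR159, miR164, miR166, miR169, miR171, miR319, miR394, miR396), nutrients (miR395, miR397, miR398, miR399, miR408, miR827, miR2111), silencing machinery (miR162, miR168, miR403), triggers of phased siRNAs (miR482, miR828, miR858, miR2118), other conserved families (miR477, miR530, miR535), and the classes predicted miRNA, siRNA and each guide length. Control lists were animal miRNAs (let-7, mir-1, mir-21) and miRNAs that match transfer or ribosomal RNA (miR894, miR1310, miR5139, miR6300, miR6478); mir-21, miR894, miR1310, miR5139 and miR6478 are not named in the table and were not analysed here.

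Shares of reads per class were compared by an exact two-sided permutation test of 3 against 3 libraries, whose smallest p is 0.1. The groups, tests, lists, most alternatives and the rule for named entries were set before the data were examined. The rule names, per contrast, every conserved family with a mean of at least 10 CPM and, among other miRNAs of at least 10 CPM with an adjusted p under the threshold, a sequence and no overlap between groups, the 5 largest rises and 5 largest falls by the fitted log2 change. A day at 0 makes that change large, so an entry picked this way need not have the largest measured change. Among siRNAs it names 3 and 3 by the same rule and, over the series, the 5 most abundant entries.

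Alternatives were RLE size factors, the upper quartile, library totals alone, totals of known miRNAs alone (called miRNA totals), other filters on low counts, the replicate number as a block, fits of 2 time points alone, DESeq2 1.42.0, a 2-fold minimum, a fit of a class alone with its own library sizes and factors, camera with an estimated correlation, fry, which tests a list against no change rather than against the other small RNAs, and leaving out each library in turn. Alternatives added after the data were seen were all reads as library size, no structural RNA entries, the values headed TPM in limma-trend on log2 (value + 1), zeros of predicted entries at 9 reads, mature and hairpin entries summed, mature entries alone for families, shares of all reads, and leaving out libraries for lists and shares. The replicate numbers do not pair the libraries, since siRNA residuals correlated between days by -0.05 to 0.07 within a number and by -0.09 to 0.07 across numbers. Within a day no 2 libraries were duplicates (chi-square per degree of freedom of 3.77 or more). The tests were tested on simulated data of 7294 entries with 200 changed, where 2-fold changes were recovered in 43%, 31% and 34% and 4-fold changes in 66%, 60% and 61% for the 3 contrasts, with 3.54%, 2.15% and 3.06% false calls. The simulated changes were few and random in direction, whereas the real contrasts called 5093, 3689 and 5741 entries. These rates therefore need not hold for the real contrasts. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.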

Results

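Small RNA was sequenced from developing seeds of the sunflower (Helianthus annuus) line L-1-OL-1, described in the labels as a high-oleic line, at 7, 22 and 37 days, with 3 libraries at each time point. The event from which the days were counted, and whether the 3 libraries of a day came from separate plants, are not given in the sources used here, so the p-values measure the spread between these libraries, which can be technical. A library held 31011803 to 34397084 reads. Entries for miRNAs, siRNAs and structural RNAs took 7.01% ± 0.196 of all reads at day 7, 10.5% ± 0.185 at day 22 and 11.9% ± 0.0765 at day 37 (SD, n = 3), which is 2208822 to 4050364 reads per library. Most other reads stood in a single total for intergenic sequence, on average 83.4% of all reads at day 7, 79.6% at day 22 and 81.1% at day 37. The comparisons ask which small RNAs differed between the 3 stages.

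Abundances below are CPM, reads scaled to the reads in small RNA entries and to TMM factors, as mean ± SD of 3 libraries, and changes are log2 ratios of the later to the earlier day with their standard error. Of 8473 small RNA entries, 7294 were tested. Their median log2 change was -0.01 from day 7 to day 22, -0.15 from day 22 to day 37 and -0.57 from day 7 to day 37, and the changes below are to be read against these medians. Scaling by library totals alone shifted the 3 medians by -0.44, -0.47 and -0.91, RLE size factors by -0.34, 0.15 and -0.19, the upper quartile by 0.07, 0.15 and 0.26, and the use of all reads as library size by 0.11, -0.28 and -0.12.

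The make-up of the small RNA pool changed with each stage. The 24-nt siRNAs, the length class that directs DNA methylation in plants, took 19.4% ± 0.624 of the reads in small RNA entries at day 7, 9.44% ± 0.575 at day 22 and 10.2% ± 0.508 at day 37 (SD, n = 3). The 21-nt siRNAs, the length of most trans-acting siRNAs, held 31.1% ± 0.466, 39.6% ± 1.19 and 35.5% ± 2.45, and the 22-nt siRNAs 20.5% ± 0.186, 19.3% ± 0.527 and 19.7% ± 1.17. Known miRNAs held 12.3% ± 0.574 at day 7, 15.4% ± 0.721 at day 22 and 7.51% ± 1.21 at day 37. Structural RNA, which is fragments of ribosomal, transfer, small nuclear and small nucleolar RNA and of other Rfam models, went from 3.72% ± 0.434 over 5.51% ± 1.37 to 17.2% ± 4.45. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow, for the 21-nt class and known miRNAs in all 3 contrasts, for the 24-nt class against day 7, and for structural RNA at day 37 against both earlier days. For the 22-nt class it was 0.1 from day 7 to day 22, 0.6 from day 22 to day 37 and 0.4 from day 7 to day 37. It was 0.3 for the 24-nt class from day 22 to day 37 and 0.2 for structural RNA from day 7 to day 22, where the libraries overlapped. Without the 10 most abundant entries the separation was lost for known miRNAs at days 22 and 37 against day 7 (exact permutation p = 0.4 and 1) and for the 21-nt class from day 22 to day 37 (0.6), while that of the 22-nt class from day 22 to day 37 was gained (0.1). For known miRNAs this loss cannot be read as dependence on abundant miRNAs. The left-out miR396f_1 ranged from 342 to 131041 reads between day 7 libraries, and miR396e-5p from 426 to 122726. The miR396 family sums there were 126090, 139248 and 130074 reads. The remaining known miRNA shares at day 7 were 6.09%, 6.49% and 11.4%.

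Counted as a share of all reads, intergenic reads included, several of these directions differed. The 24-nt class held 1.36%, 0.988% and 1.22% of all reads at days 7, 22 and 37, the 21-nt class 2.18%, 4.15% and 4.24%, and the 22-nt class 1.43%, 2.02% and 2.36%. All siRNA entries together held 79.0%, 74.6% and 73.0% of the reads in small RNA entries, but 5.53%, 7.82% and 8.71% of all reads. Known miRNAs at day 37 lay under day 7 in the first measure, but held 0.898% of all reads at day 37 and 0.860% at day 7.

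**Figure D1:**
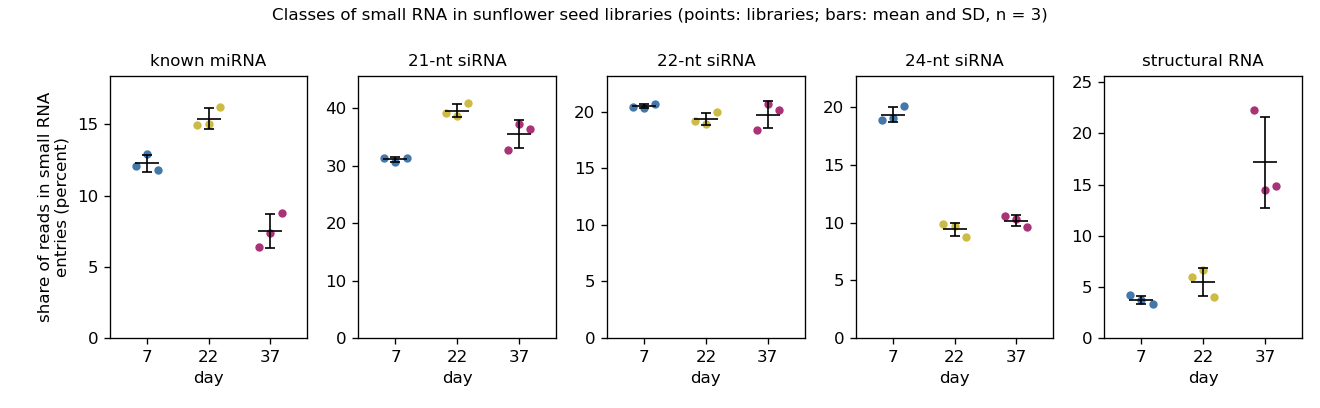
Percent of the reads in small RNA entries taken by known miRNAs, 21-nt, 22-nt and 24-nt siRNAs and structural RNA at days 7, 22 and 37; points are libraries, bars the mean and SD of 3. The 24-nt class held 19.4% at day 7 and 9.44% at day 22, and structural RNA 17.2% at day 37.

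From day 7 to day 22, 17 of 23 conserved miRNA families rose, among them miR156, a repressor of SPL transcription factors that keeps plants in their juvenile phase. The miR156 family went from 1340 ± 101 to 9203 ± 1036 CPM, a 6.87-fold rise (log2 2.78, SE 0.12, adjusted p = 3.78e-08). The family miR397, which targets laccases, rose 7.09-fold from 37.1 ± 7.76 to 264 ± 18.7 CPM, and miR168, which targets the silencing protein AGO1, rose 3.37-fold from 7920 ± 904 to 26675 ± 2765 CPM. In the other direction, miR162, which targets the miRNA-processing enzyme DCL1, was 3.09-fold lower at day 22 (log2 -1.63, SE 0.18, adjusted p = 2.6e-05), and miR393, which targets auxin receptors of the TIR1 group, was 2.57-fold lower (206.5 ± 21.3 to 80.2 ± 11.8 CPM). Of the other 6 families 2 were lower and 4 did not pass, and the calls were the same adjusted over the list alone and together with all entries. The split of 17 rises and 2 falls was 14 and 4 with library totals alone and 11 and 9 with miRNA totals. All 3 day 22 libraries shared the direction in each called family, which a call at n = 3 nearly requires. Family values join mature and hairpin entries. In miR169, miR172, miR393, miR394 and miR477 the most abundant entry was a hairpin, so their changes need not be those of the mature miRNA.

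Both phase-change families rose by day 22, miR156 as above and miR172, a regulator of AP2-like flowering genes, by 1.05 on the log2 scale (20.8 ± 1.30 to 43.1 ± 4.95 CPM), although miR172 was lower by 0.98 when mature entries alone were counted. Of 4 auxin-related families, miR160 (1.97-fold), miR167 (2.29-fold) and miR390 (2.17-fold) rose and miR393 fell, with miR390 at log2 3.35 with mature entries alone, since its hairpin entry fell. The first pair target auxin response factors, and miR390 starts trans-acting siRNAs against others of that group. Among 8 families that target developmental transcription factors and related regulators, 5 rose and 3 did not pass. The risers included miR171 (GRAS factors, log2 1.78, SE 0.07), miR169 (NF-YA, 1.73), miR394 (1.63) and miR164 (NAC factors, 1.21, 3136 ± 158.8 to 7274 ± 782 CPM). The most abundant, miR396, which targets growth-regulating factors, rose by 0.39 (42405 ± 1447 to 55409 ± 5057 CPM, adjusted p = 0.0164), but its change was -0.06 with library totals alone and -0.40 with miRNA totals. The changes of miR159, miR166 and miR319 were 0.38, 0.01 and 0.07 without passing, and turned to -0.41, -0.78 and -0.72 with miRNA totals; miR166 was also at -0.34 with RLE factors and -0.44 with library totals.

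Of 4 nutrient families, miR397, miR399 (phosphate starvation, log2 1.57) and miR398 (copper and oxidative stress, 0.41) rose, while miR395 (sulfate) stood at 0.04; miR398 turned to -0.03 with library totals and -0.38 with miRNA totals, and miR395 to -0.74 with miRNA totals. In the silencing group miR168 (log2 1.75) and miR403 (AGO2, 1.45) rose and miR162 fell. The phasiRNA trigger miR858 rose by 0.33, with changes of -0.02, -0.12 and -0.46 under RLE factors, library totals and miRNA totals, and miR477 rose by 3.14 from 5.47 ± 0.475 to 48.5 ± 13.9 CPM. As sets against the other small RNAs (camera), the phase-change list (adjusted p = 0.000479), the silencing list (adjusted p = 0.0109) and the developmental list (adjusted p = 0.0413) moved up, and each call was lost at adjusted p = 0.148 with an estimated correlation, within a range of 0.000233 to 0.451 over the camera settings of these lists. The number of lists and classes called, 7, was reached by 4 of 10 splits of these 6 libraries, the real one included. The highest other split called 8, so that number does not set the real days apart. Of the 182 entries behind the lists, 101 passed over all small RNAs and 98 adjusted over the list alone. With miRNA totals the calls of miR160 (log2 0.19), miR172 (0.26) and miR390 (0.33) were lost. With RLE factors those of miR396 (0.04) and miR398 (0.07) were lost. The miR159 family gained a call with all reads as library size (0.49) and miR166 with mature entries alone (0.56). The miR396 call was lost without day 7 replicate 1, 2 or 3 or day 22 replicate 3 (adjusted p 0.073 to 0.116), the miR398 call without day 7 replicate 2 or 3 (0.0787 to 0.0808), and miR159 gained one at log2 0.54 without day 22 replicate 3 (adjusted p = 0.000432).

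Known miRNA entries taken singly were higher at day 22 in 46 of 97 cases and lower in 10, and predicted miRNAs were higher in 17 of 43 and lower in 14, which makes 63 higher and 24 lower of 140. In 54 of 270 pairs of a known miRNA or hairpin entry and a day, the libraries lay at least 10-fold apart. This limits the single-entry counts in all 3 contrasts and is taken up below. Precursor overlaps joined 14 of all predicted miRNAs, which were counted as separate entries where tested. The percent higher among called miRNAs was 72.4, against 47.1 when miRNAs were scaled as a class alone. Entries below are picked by their fitted change, which runs high where a day is at 0, so they are not ranked by size. Rises picked among predicted miRNAs were novel_mir69 (GGTGATCGGGTGAGACGTATGTACC, 181723914 to 181724057 on NC_035445.1), listed at 0 reads in all day 7 libraries and at 109 ± 26.0 CPM at day 22, and novel_mir38 (AAGCTGCCAGCATGATCTATCTTG, 21082190 to 21082289 on NC_035442.1), at 0 and 13.4 ± 4.40 CPM. If a 0 allows at most 9 reads, as assumed for entries listed only from 10 reads, these rises were 37.8-fold or more and 4.63-fold or more. All folds given below as at least a value rest on that assumption. The others were novel_mir9 (ACGTTGAGCCTTAAGACCAGCTAGG, 55117526 to 55117854 on NC_035435.1, log2 3.90, SE 0.19), novel_mir98 (CAGCCTGCCCACCCTGGAAACGACT, 2832 to 3047 on NW_019010134.1, 3.16, SE 0.44) and novel_mir59 (CGCGACGTCGCGAGAATTCCACTGAACCT, 161563937 to 161564124 on NC_035444.1, 2.87, SE 0.97, adjusted p = 0.0267). Of these, novel_mir59 lies in small-subunit ribosomal RNA sequence, novel_mir98 resembles large-subunit ribosomal RNA and novel_mir38 overlaps miR167 with a shift. Mature lengths were 25 nt for novel_mir9, novel_mir69 and novel_mir98 and 29 nt for novel_mir59, longer than the siRNA lengths above. Predicted miRNAs named in this report ran from 20 nt (novel_mir60, novel_mir84) to 30 nt (novel_mir57, novel_mir71, novel_mir78). That such entries are miRNAs rather than fragments was not tested, and the miRNA counts include them. The novel_mir59 call was lost without day 7 replicate 2 or 3 or day 22 replicate 1 or 2 (log2 2.07 to 2.94, adjusted p 0.0503 to 0.0948).

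Falls picked were novel_mir22 (ATGGAATGTGTGGCTTCGAACAAA, 34348343 to 34348478 on NC_035437.1), from 119 ± 25.4 CPM to between 0 and 12 reads (log2 -5.29 with zeros at 9 reads), and novel_mir84 (ACAATCAAAAGCATGTGGTA, 20192413 to 20192580 on NC_035447.1), from 89.7 ± 9.16 to 8.13 ± 1.60 CPM. The others were novel_mir82 (TCAACATGTGTTTATAGCTAAT, 18721656 to 18721944 on NC_035447.1, log2 -2.98), novel_mir35 (TTTGGGCCGAGGTTATCATGAACCGG, 123485519 to 123485689 on NC_035441.1, -2.87, or -2.48 with zeros at 9 reads) and novel_mir71 (TTTGAGCTTTTTATGTCACGGTGTATTACT, 52355969 to 52356257 on NC_035446.1, -2.37), the last of which did not pass with the values headed TPM (adjusted p = 0.0581). All precursors named here lie on the plus strand. The genome build is not given in the sources used here and the intervals, if counted from 1, are 1 base longer than the precursors, so the positions are given as deposited and were not set against genes.

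The siRNAs split by length between day 7 and day 22. Among 24-nt siRNAs 1568 of 2521 were lower at day 22, and 9.05% of the calls were rises, while among 21-nt siRNAs 1399 of 2500 were higher and 394 lower, and among 22-nt siRNAs 780 of 1572 were higher and 365 lower. The median log2 change was -1.44 for 24-nt, 0.92 for 21-nt and 0.76 for 22-nt siRNAs, and -1.05, 0.82 and 0.56 with zeros at 9 reads. As sets the 24-nt class moved down (adjusted p = 1.13e-36; adjusted p = 0.000646 with an estimated correlation), the 21-nt class up (7.58e-14; 0.0108) and the 22-nt class up (4.87e-05; 0.0439), and siRNAs as a whole moved down (0.00163; 0.0314). The limit from other splits of the libraries, given above, holds for these set calls too. In all contrasts the sets by length also held predicted miRNAs of that length, with 2528, 2501 and 1577 entries at 24, 21 and 22 nt. Over all lengths 2429 of 6953 siRNAs were higher and 2478 lower, so that 49.5% of the calls were rises, against 38.8% with library totals alone. The rises picked by fitted change were novel_sir16802 (TCGGATGGCTATGCAAACACC), novel_sir1016 (ACGGAGTTCCACTATAGCTAG) and novel_sir9288 (CAGCGTTGTCGACAAGAGCCTT), all listed at 0 at day 7 and at least 79.9-fold, 60.9-fold and 58.5-fold higher at day 22 against 9 reads. The falls so picked were novel_sir5909 (AAGGATTCCAACGGTGCAAACGGT), novel_sir9897 (GATGGCCAAAGGAGAATACCT) and novel_sir4420 (AGCTAGGGGTGTTCAAGATCGGAT), at 0 at day 22 and at least 83.7-fold, 80.8-fold and 71.2-fold lower. Among structural RNAs, 24 of 41 small nucleolar RNAs were higher and 1 lower, with a median log2 change of 1.54.

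**Figure D2:**
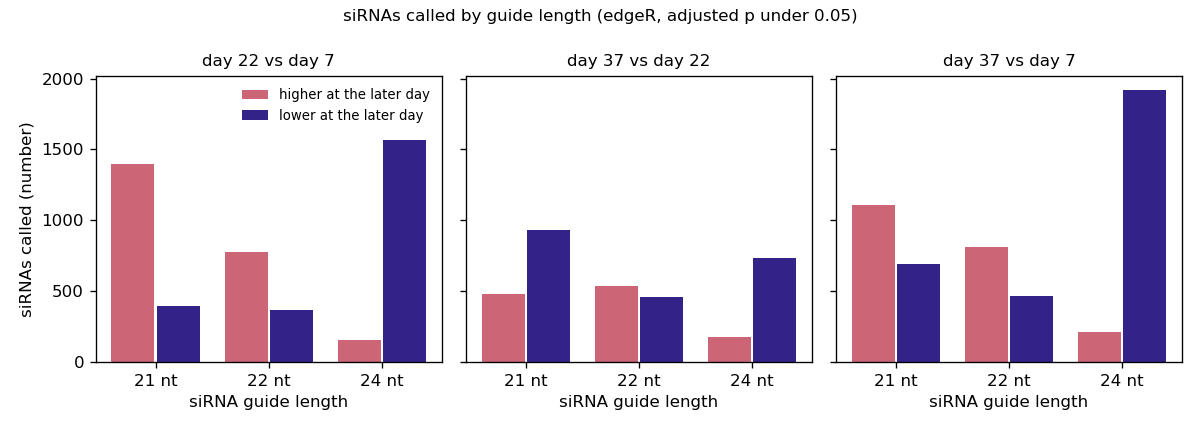
Number of 21-nt, 22-nt and 24-nt siRNAs called higher or lower at the later day in each contrast (edgeR, adjusted p under 0.05; bars are counts of siRNAs). From day 7 to day 22, 1568 of the 24-nt siRNAs were lower, while 1399 of the 21-nt siRNAs were higher and 394 lower.

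From day 22 to day 37, a group of miRNA families fell steeply. The miR396 family dropped 14.4-fold, from 55409 ± 5057 to 3848 ± 671 CPM (log2 -3.85, SE 0.14, adjusted p = 1.44e-08), miR399 15.8-fold, from 166.01 ± 48.0 to 10.4 ± 2.42 CPM, and miR477 11.9-fold, from 48.5 ± 13.9 to 4.08 ± 1.14 CPM. Further falls were those of miR164, whose NAC targets set organ boundaries, at 7.64-fold (7274 ± 782 to 952 ± 133 CPM), the auxin-receptor regulator miR393 at 7.27-fold (80.2 ± 11.8 to 11 ± 1.47 CPM) and the AGO2 regulator miR403 at 4.62-fold (941 ± 37.1 to 204 ± 9.47 CPM). In miR393 and miR477 a hairpin was the most abundant entry, so these falls need not be those of the mature miRNA. The families that rose were fewer: miR169 2.12-fold (144 ± 19.2 to 305 ± 82.5 CPM), miR167 1.66-fold (17733 ± 2291 to 29493 ± 7044 CPM) and miR171 1.22-fold, the last turning to -0.19 with library totals alone and -7.89e-05 with all reads as library size. Of 23 families 3 rose, 11 fell and 9 did not pass, the same adjusted over the list alone and with all entries. All 3 day 37 libraries shared the direction in each called family, as a call at n = 3 nearly requires. The structural RNA share rose over the same interval from 5.51% to 17.2% of the reads in small RNA entries.

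By list, the auxin group had 1 rise (miR167), 1 fall (miR393) and 2 families that did not pass, miR160 at log2 0.20 and miR390 at -0.29. The developmental group had 2 rises (miR169, miR171), 3 falls (miR164, miR166, miR396) and 3 without a call, miR159 at 0.18, miR319 at -0.41 and miR394 at -0.74. Here miR166, which targets HD-ZIP III factors, fell by 0.32, but its change was 0.21 with miRNA totals and 0.23 with mature entries alone. The nutrient group had 2 falls, miR399 and miR398 (log2 -0.96), and miR395 at -0.49 and miR397 at -0.07 without a call, the latter turning to 0.47 with miRNA totals. In the silencing group miR168 fell 1.99-fold (26675 ± 2765 to 13385 ± 1298 CPM) with miR403, and miR162 stood at 0.31. In the phase-change group miR172 fell 3.01-fold (43.1 ± 4.95 to 14.4 ± 4.34 CPM) and miR156 stood at 0.27 (adjusted p = 0.0655). The trigger miR858 fell by 0.50, with a change of 0.03 under miRNA totals. No family list moved as a set (lowest adjusted p = 0.181), and of the 182 list entries 80 passed over all small RNAs and 79 adjusted over the list alone. The auxin list had a median of 0.30 and a mean of -0.17.

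Single libraries and the scaling decided some of these calls. The miR166 call was lost without day 7 replicate 1, day 22 replicate 1 or 2 or day 37 replicate 2 or 3 (adjusted p 0.0508 to 0.0875) and the miR167 call without day 22 replicate 1 or day 37 replicate 3 (0.0635 to 0.0778). The miR167 call was also lost with library totals alone (log2 0.27) and with all reads as library size (0.46), the miR166 call with RLE factors (-0.17) and the miR169 call with mature entries alone (0.32). Calls were gained by miR156 with RLE factors or miRNA totals (0.42 and 0.79) and by miR159, miR160 and miR162 with miRNA totals (0.71, 0.70 and 0.85). They were also gained by miR397 with library totals alone (-0.54) or, upwards, miRNA totals (0.47). With library totals alone or all reads as library size, calls were gained by miR319, miR390, miR394 and miR395 (-0.88, -0.75, -1.19 and -0.97 with library totals), and by miR394 also with the replicate number as a block (-0.86, adjusted p = 0.029). Without day 22 replicate 3 or day 37 replicate 1 miR156 passed (0.0138 to 0.0208), without day 37 replicate 3 miR319 (0.00406) and miR394 (0.00146), and without day 37 replicate 1 miR395 (0.046). Of the called families 3 of 14 were rises, against 8 rises and 9 falls with miRNA totals, 1 and 18 with library totals alone, and 1 and 15 with all reads as library size.

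Single known miRNA entries were higher at day 37 than at day 22 in 16 of 97 cases and lower in 23, and predicted miRNAs were higher in 13 of 43 and lower in 9, together 29 higher and 32 lower of 140. With library totals alone the split was 20 higher and 41 lower, and with miRNAs scaled as a class alone 15 and 34. Rises picked by fitted change were novel_mir92 (AGTTGGTTAGGATACTCGGCTCTCACCC, 36276857 to 36276957 on NC_035449.1), at 0 reads at day 22 and at least 20.7-fold higher at day 37, novel_mir78 (CACAAGCTGGCTTGCCCGTTCCAAGTTGTG, 127169788 to 127170073 on NC_035446.1, log2 3.54, SE 0.64) and novel_mir8 (GACGACTTAAATACGTGACGGGGTATTGT, 11208490 to 11208717 on NC_035435.1, 3.07, SE 0.83, adjusted p = 0.0142). Further ones were novel_mir60 (CCTACCGATTGAATGGTCCG, 161886360 to 161886557 on NC_035444.1, log2 2.32, 123 ± 16.2 to 613 ± 125 CPM) and novel_mir58 (TTAGGATCGTGGCGACGTGGGCGGTTC, 152635547 to 152635747 on NC_035444.1, log2 2.19). The precursors of novel_mir58, novel_mir59 and novel_mir60 contain each other's mature sequences and are small-subunit ribosomal RNA sequence, novel_mir92 resembles a transfer RNA for glutamate, and novel_mir8 resembles large-subunit ribosomal RNA, so these rises stand beside that of structural RNA. The novel_mir8 call was lost without day 22 replicate 3 (log2 2.81, adjusted p = 0.0526) and with the values headed TPM (adjusted p = 0.107).

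Falls picked by fitted change were novel_mir9, novel_mir25 (CTGACATGGTATGAGAGTAGTTAA, 132815177 to 132815250 on NC_035437.1), novel_mir84 and novel_mir82, all at 0 reads at day 37 and at least 19.2-fold, 9.60-fold, 2.53-fold and 1.40-fold lower than at day 22. The novel_mir82 call was lost with zeros at 9 reads (log2 -0.42, adjusted p = 0.372). In novel_mir57, also picked (TGGCAGTCCAAGTAGTAGCGGGGGAGTCAT, 152230715 to 152231141 on NC_035444.1) the fall was from 187 ± 15.3 to 25.4 ± 2.58 CPM (log2 -2.88, SE 0.12).

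Most siRNA calls between day 22 and day 37 were falls, 2253 against 1280 rises of 6953. Falls outnumbered rises in the 24-nt class, with 734 of 2521 lower and 177 higher, and in the 21-nt class, with 929 of 2500 lower and 483 higher, while the 22-nt class had 536 of 1572 higher and 462 lower. Median log2 changes were -0.17, -0.33 and 0.08, and 0.18, -0.16 and 0.31 with zeros at 9 reads, so the median of the 24-nt class turned with the listing minimum. The 22-nt class moved up as a set (adjusted p = 0.0167), a call that was lost at adjusted p = 0.288 with an estimated correlation (0.00559 to 0.288 over the camera settings), and its mean change was -0.23 where its median was 0.06. Tested by fry against no change, the class moved down (adjusted p = 2.89e-05). As many sets called by camera as in the real grouping, 1, were reached by 8 of 10 splits of these libraries. Library totals alone lowered the share of rises from 36.2% to 23.1% over all siRNAs, from 34.2% to 20.0% in the 21-nt class and from 53.7% to 41.0% in the 22-nt class. Rises picked by fitted change were novel_sir15571 (GCCTCTAAGTCAGAATCCATG), novel_sir19385 (TAACCAAGGGCCAAATCGCAAAGT) and novel_sir10844 (ATTTAGCCTTGGACGGAATTTACC), at 0 at day 22 and at least 32.6-fold, 31.02-fold and 30.2-fold higher at day 37. Falls so picked were novel_sir16603 (AGCGGTCTCCTTCTACACATG), novel_sir7470 (CTGTAAACATGCTCAAGTTCAA) and novel_sir12006 (CGAGAGCTTGTTACCCGATAAG), at 0 at day 37 and at least 33.5-fold, 29.7-fold and 28.2-fold lower. All 9 ribosomal RNA entries were higher at day 37 (median log2 2.19), as were 24 of 41 small nucleolar RNAs against 1 lower.

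Between the ends of the series, day 7 and day 37, conserved families moved in both directions. The miR156 family was 8.29-fold higher at day 37 (1340 ± 101 to 11106 ± 1191 CPM, log2 3.05, SE 0.12, adjusted p = 1.23e-08), miR169 7.03-fold (43.4 ± 7.01 to 305 ± 82.5 CPM), miR397 6.77-fold (37.1 ± 7.76 to 252 ± 29.8 CPM), miR171 4.19-fold and miR167 3.81-fold. In the other direction, miR393 was 18.7-fold lower (206.5 ± 21.3 to 11 ± 1.47 CPM), miR396 11.02-fold lower (42405 ± 1447 to 3848 ± 671 CPM), miR399 5.32-fold lower and miR164 3.29-fold lower. The most abundant entry of miR393, and also of the rising miR169, was a hairpin. Of 23 families 10 were higher, 8 lower and 5 without a call, the same adjusted over the list alone and with all entries. All 3 day 37 libraries shared the direction in each called family but miR394, in which 2 of 3 lay above every day 7 library.

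Of the auxin families miR160 (log2 1.18), miR167 (1.93) and miR390 (0.83) were higher and miR393 (-4.22) was lower, with miR390 at -0.08 under library totals alone and 3.23 with mature entries alone. The developmental group split into 4 rises and 3 falls. Its rises were miR169 (log2 2.81, or 1.69 with mature entries alone), miR171, miR159 (log2 0.56) and miR394 (0.89), of which miR159 and miR394 turned to -0.36 and -0.02 with library totals. Its falls were miR164, miR396 and miR166 (-0.32, but 0.79 with mature entries alone), and miR319 stood at -0.34. In the nutrient group miR397 was higher, miR399 and miR398 (-0.55) lower and miR395 at -0.45. Silencing-related families had 1 rise, miR168 at log2 0.76 and at -0.16 with library totals, and 2 falls, miR162 (-1.32) and miR403 (-0.76). Neither miR172 (log2 -0.54, adjusted p = 0.0531), miR858 (-0.17, adjusted p = 0.0531) nor miR477 (-0.43) passed. Both miR172 and miR858 were called lower under 5 other settings (log2 -3.12 to -0.69 and -1.09 to -0.17). These were RLE factors, library totals alone, miRNA totals, mature entries alone and all reads as library size.

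As a set the phase-change list moved up (adjusted p = 0.000894), a call lost at adjusted p = 0.212 with an estimated correlation, within 0.000578 to 0.212 over its camera settings. The number of lists and classes called, 5, was reached by 7 of 10 splits of these libraries, with 9 as the highest other. That number does not set the real days apart. Of 182 list entries 111 passed over all small RNAs and 107 adjusted over the list alone. The developmental and nutrient lists had negative medians (-0.11 and -0.46) and means (-0.07 and -0.57) beside a test direction of up at adjusted p = 0.29 and 0.92, and the trigger list a median of -0.17 and a mean of 0.24. Calls were lost for miR159 without any one day 7 library or day 37 replicate 2 or 3 (adjusted p 0.0658 to 0.0876), for miR166 without day 37 replicate 2 or 3 (0.0684 to 0.0742) and for miR394 without any one library but day 37 replicate 1 (0.0505 to 0.146). With library totals alone the miR160 call was lost (log2 0.26) and miR477 gained one (-1.35). With RLE factors, miRNA totals, mature entries alone or all reads as library size the miR159 call was lost (0.30 to 0.42). The miR394 call was lost with RLE factors, mature entries alone or all reads (0.53 to 0.76). In turn, miR319 passed with RLE factors, library totals or miRNA totals (-1.25 to -0.53) and miR395 with library totals or miRNA totals (-1.37 to -0.70). With a library left out, calls were gained for miR319 without day 37 replicate 3 (0.00617), for miR395 without day 37 replicate 1 (0.0465), for miR172 without day 22 replicate 3 or day 37 replicate 1 (0.00604 to 0.0449) and for miR858 without day 7 replicate 2 or 3 or day 22 replicate 3 (0.00777 to 0.0468). The share of rises among called families was 42.1% with RLE factors, 26.3% with library totals, 42.9% with miRNA totals and 44.4% with all reads as library size.

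**Figure D3:**
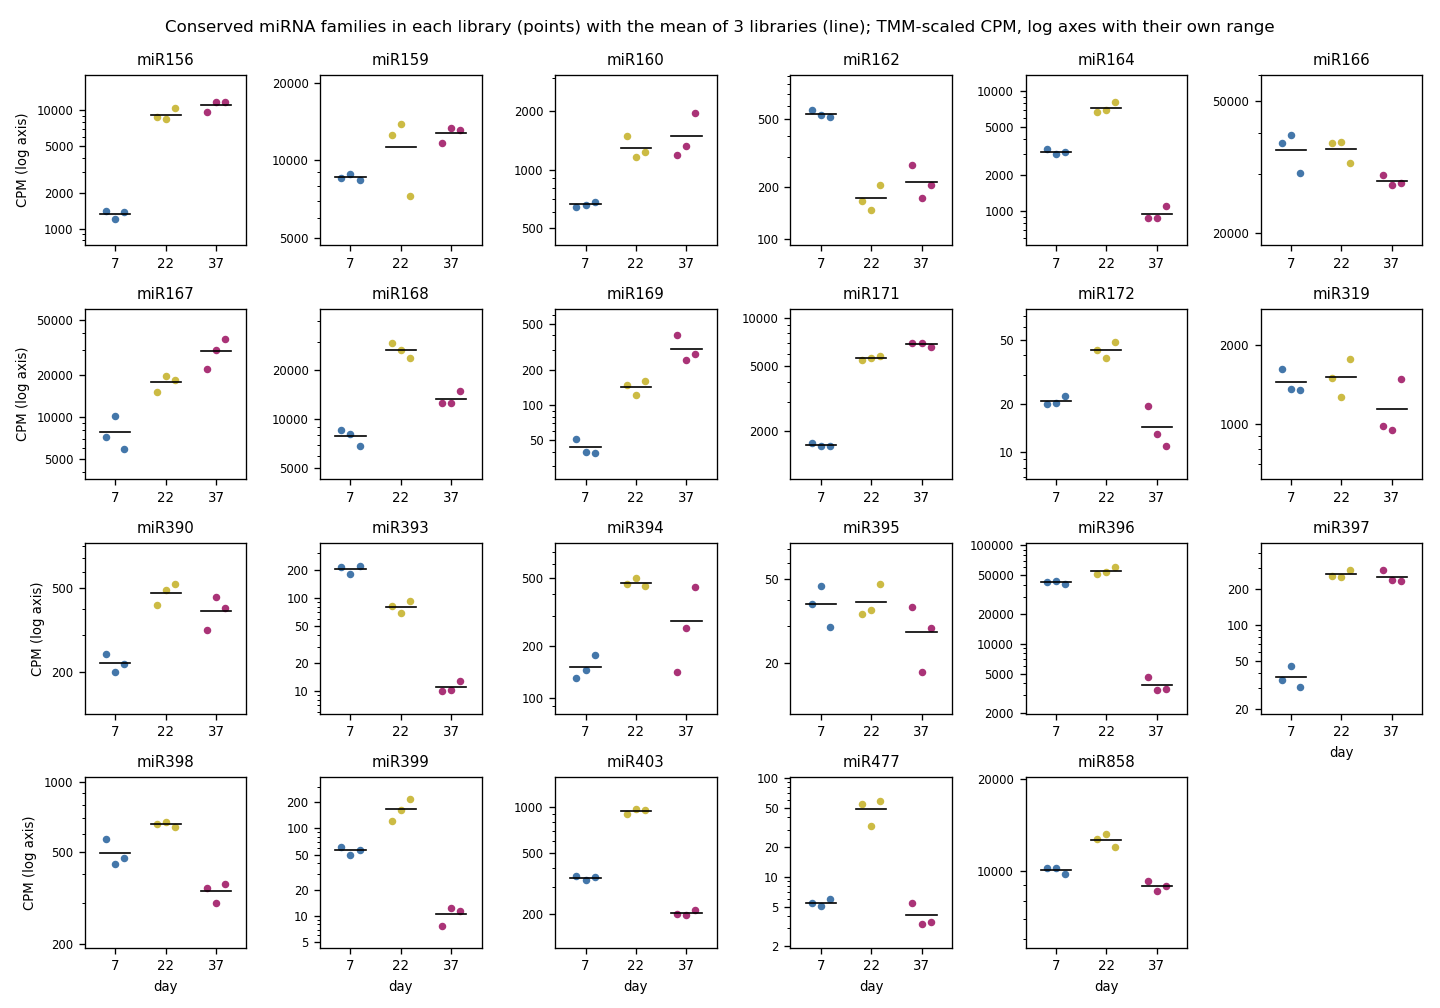
TMM-scaled CPM (log axes, each with its own range) of the 23 conserved miRNA families at days 7, 22 and 37; points are libraries and lines the mean of 3. The miR156 means were 1340, 9203 and 11106 CPM, and those of miR396 42405, 55409 and 3848 CPM, although the change of miR396 from day 7 to day 22 turned to -0.06 with library totals alone and -0.40 with miRNA totals.

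Known miRNA entries were higher at day 37 than at day 7 in 39 of 97 cases and lower in 19, and predicted miRNAs were higher in 23 of 43 and lower in 17, together 62 and 36 of 140. The share of rises was 63.3%, against 50.0% with library totals alone and 45.2% with miRNAs scaled as a class alone. Predicted miRNAs picked by fitted rise were novel_mir69 (0 to 269 ± 59.9 CPM, at least 92.6-fold), novel_mir92 (at least 18.3-fold), novel_mir38 (at least 6.80-fold), novel_mir78 (log2 6.23, SE 0.84, or 5.06 with zeros at 9 reads) and novel_mir8 (4.28, SE 0.92, or 4.23), in no order of size. Those picked by fitted fall, all at 0 at day 37, were novel_mir22 (at least 37.1-fold), novel_mir84 (at least 28.0-fold), novel_mir82 (at least 11.1-fold), novel_mir25 (at least 10.1-fold) and novel_mir9 (at least 1.27-fold). The novel_mir9 call was lost with zeros at 9 reads (log2 -0.21, adjusted p = 0.613). Since novel_mir9 stood at 61.5 ± 6.25 CPM at day 22 and at 4.07 ± 0.839 CPM at day 7, it was most abundant at day 22.

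The 24-nt siRNAs were the class with the widest loss between day 7 and day 37, with 1922 of 2521 lower and 212 higher. Among 21-nt siRNAs 1110 of 2500 were higher and 694 lower, and among 22-nt siRNAs 811 of 1572 were higher and 467 lower. The median log2 change of the 24-nt class was -3.58, or -1.36 with zeros at 9 reads, and those of the 21-nt and 22-nt classes were 0.45 and 0.79. As sets the 24-nt class moved down (adjusted p = 5.38e-25; 0.00197 with an estimated correlation), as did siRNAs as a whole (0.000365; 0.0266), and the 21-nt (2.05e-06; 0.0405) and 22-nt (2.05e-06; 0.0302) classes moved up. For these set calls too, the number of sets called does not set the real days apart from other splits of the libraries. With library totals alone the 21-nt class turned to 689 higher and 1042 lower and the 22-nt class to 621 higher and 640 lower, and the share of rises over all siRNAs (2247 higher, 3257 lower) went from 40.8% to 27.1%. The rises picked by fitted change were novel_sir1016, novel_sir14422 (TAAACGTTACCAGATAGTCATG) and novel_sir5239 (AAAAGGTCCTATGTATCGCGGG), at 0 at day 7 and at least 218-fold, 163-fold and 152-fold higher. The falls so picked were novel_sir825 (AAACGAGTCAAAGGGTAGGTCTTG), novel_sir264 (AAGAACCGGATGAAGTAGAATTCT) and novel_sir7554 (GAAATTTCGGATACGGATTCGG), at 0 at day 37 and at least 178-fold, 174-fold and 136-fold lower. Small nucleolar RNAs were higher at day 37 for 39 of 41 entries and lower for 1 (median log2 3.09), and all 9 ribosomal RNA entries were higher (median log2 3.09).

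Over the 3 time points together, 6114 of 7294 small RNAs changed. Of the changed 24-nt siRNAs 1846 of 2119 (87.1%) were most abundant at day 7, of the 21-nt siRNAs 846 of 2091 (40.5%) at day 22 and of the 22-nt siRNAs 687 of 1355 (50.7%) at day 37. Changed miRNAs had their highest mean at day 7 in 29 of 105 cases, at day 22 in 27 and at day 37 in 49. The 24-nt pool also narrowed, as a library listed 2598 ± 54.1 24-nt siRNAs at day 7, 1602 ± 22.8 at day 22 and 1211 ± 37.5 at day 37, and its 10 most abundant entries took 10.1%, 20.4% and 27.5% of the 24-nt reads. A larger part in the 10 most abundant was not particular to this class. It went from 25.2% over 35.2% to 36.4% at 22 nt and from 20.0% over 27.6% to 23.9% at 21 nt. The 5 most abundant entries of the series were the eukaryotic small-subunit ribosomal RNA model (18341 ± 2233, 35903 ± 8795 and 146241 ± 33162 CPM at days 7, 22 and 37), miR396f_1 (27138 ± 23414, 53006 ± 4905 and 2527 ± 2258 CPM) and 3 siRNAs. Of these, novel_sir15071 (ATCGAACAGGTTCAAGGCATC) was at 13131 ± 2448, 32579 ± 3785 and 12446 ± 1768 CPM, novel_sir17151 (TAAACATCCATTGAGCCTAAGA) at 1263 ± 165.98, 12779 ± 331 and 38892 ± 1965 CPM, and novel_sir14147 (TGAAAGCAACATGTTGTTCAGT) at 11935 ± 736, 20923 ± 1131 and 17959 ± 1222 CPM.

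Among control entries, the let-7 and mir-1 precursor models held 0 to 1 reads per library, while animal-named precursor models together 196 to 928 reads. The breakdown-related miR6300 held 105 to 251 reads per library, with no separation by day in its mature entry, and its hairpin 132 to 145 reads at day 22 and 211 to 244 at day 37. These counts reach those of some families above, such as miR172 (31 to 186 reads), miR395 (54 to 183) and miR477 (10 to 226). The families miR408, miR482, miR535, miR827, miR828, miR2111 and miR2118 were not named in the table and were not analysed here, and miR530, at 2 to 11 reads per library, was too scarce to be among the 23.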

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

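The tests and their bounds in this part were chosen only after the results were seen.

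Known miRNA entries lay far apart between libraries of one day. In 54 of 270 pairs of an entry and a day with at least 100 reads (20.0%) the libraries spread at least 10-fold, as in miR396f_1 at day 7 (342 to 131041 reads) beside miR396e-5p (426 to 122726 reads), while 0 of 62 family sums did so (highest ratio 3.41), and siRNAs, which noise common to abundant entries would reach too, did so in 1 of 7277 pairs (0.01374%). A candidate explanation is that reads of one family moved between its near-identical entries, since in 46 of the 54 (85.19%) another entry of the family moved at least 10-fold the other way by at least 0.2 of the reads. Several forms of this test were computed before that one was kept: by any amount of reads it held for 49 of 54 (90.7%), but the other entries of the family together rose by at least 0.5 of the fall for 38 of 54 (70.4%), short of the bound of 80% set for the kept form. The spread of miR536-3p at day 37 (3441 to 34903 reads) had no such partner, and no biological explanation was tested. Whether the libraries of a day came from separate plants is not given, so differences between plants stay open.

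Structural RNA was higher at day 37 than at day 7, with 0.261% of all reads at day 7, 0.575% at day 22 and 2.05% at day 37. A single library is argued against, since without the highest day 37 library, replicate 1, the ratio to day 7 was still 6.71. Breakdown of all RNA classes alike is argued against by small nuclear RNA alone, whose ratio was 1.457 (1.23 to 1.72 between libraries) where those of ribosomal, small nucleolar and transfer RNA were 8.04 (5.97 to 12.01), 5.74 (4.21 to 8.09) and 50.4 (12.3 to 189), and bacterial RNA as the main source is argued against because eukaryotic ribosomal RNA made up 88.15% of the rise. For the rest of the rise bacterial RNA stays open, since the transfer-messenger RNA model, known from bacteria, rose too, from 3536 to 47071 mean reads (log2 3.90, SE 0.46, adjusted p = 7.71e-05). The bacterial small-subunit and large-subunit ribosomal RNA models held fewer reads than it, with rises from 452 to 3112 and from 370 to 2123 mean reads. The organism or organelle behind these models was not tested. Breakdown of some RNA classes more than others, and a developmental change in the seed, stay open as untested and may act together.

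The 24-nt siRNAs were lower at day 37 than at day 7, in 1922 of 2521 cases. The choice among the scalings used as the cause is argued against, since over 6 other scalings at least 88.42% of the called 24-nt siRNAs were lower. Among the shifts of the median given above for this contrast, only that of the upper quartile was upward, by 0.26. These scalings therefore say little about a larger upward shift. The listing minimum as the whole cause is argued against, since with zeros taken as 9 reads on both days the median log2 change of all 2521 was -1.359, and that of the 1021 with at least 100 reads on either day -1.61, where 21-nt and 22-nt siRNAs chosen alike had 0.91 and 1.08. As a share of all reads the class held 1.36% at day 7 and 1.22% at day 37, so the fall concerns most listed 24-nt siRNAs more than the class as a whole, whose 50 most abundant entries took 25.9% and 64.6% of its reads. That the seeds held fewer of these siRNAs late in development is a hypothesis found and tested on the same data, and intergenic reads outside the listed entries, which the table does not split by length, may hold further ones.

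The columns headed TPM, not used in the main tests, fell to 0.424 of the count in the most abundant known miRNAs and to 0.571 in the most abundant siRNAs, where they lay lowest, with medians of 0.872 and 0.944.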

How the results depend on the processing

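The shares of all reads, mature entries alone, all reads as library size, values headed TPM, zeros at 9 reads, fits without structural RNA, summed mature and hairpin entries and the left-out libraries for lists and shares were chosen after the data were seen; the other alternatives were set before. Counts of calls stayed within 1.5 times in 196 of 198 cases with a library left out and in 231 of 241 other cases. The ranges with a library left out were 80 to 94, 58 to 64 and 93 to 102 miRNAs, 4624 to 5028, 3164 to 3356 and 5328 to 5472 siRNAs, 17 to 19, 12 to 16 and 15 to 20 families for day 22 against 7, 37 against 22 and 37 against 7, and 5839 to 5984 small RNAs over time. Without day 22 replicate 2 or day 37 replicate 2 the siRNA set passed from day 22 to day 37, which took the functional lists there from 1 to 2. Named siRNAs kept call and direction in 162 of 162 cases with a library left out and 216 of 216 others. Named predicted miRNAs did so in 265 of 270 and 356 of 360, the rest losing the call. These entries were picked for passing, for separated groups and for large fitted changes, and each named siRNA was at 0 on a whole day. Their stability therefore says little about the other calls. Families kept call and direction in 580 of 621 with a library left out (28 lost and 13 gained a call) and in 336 of 411 others (17 lost, 33 gained, 25 reversed). Class-share ratios stayed within their spread in 126 of 126 cases with a library left out and in 13 of 42 others. With the replicate number as a block, calls were 83, 59 and 91 miRNAs, 3997, 2977 and 4797 siRNAs, 19, 15 and 18 families and 5131 over time.

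The functional lists called from day 7 to day 22 went from 7 to 4 with an estimated correlation and to 4 with family sums, which tested 9 sets in place of 12, since phase change, called before, and 2 uncalled lists had fewer than 3 families. From day 22 to day 37 they went from 1 to 0 with an estimated correlation, 11 with fry, which tests against no change, 2 with the replicate block and 2 with family sums, and from day 7 to day 37 from 5 to 9 with fry. The 21-nt siRNAs called higher from day 22 to day 37 went from 483 to 311 with library totals alone and 315 at 2-fold or more, and from day 7 to day 37 from 1110 to 689 with library totals alone. The fry direction was down where camera's was up for the auxin list (adjusted p 0.000507 and 0.00339 for day 37 against 22 and 7), the predicted miRNAs (0.000239 and 0.000306) and, for day 37 against 22, the 22-nt class (2.89e-05). The cause was not tested, except that a 2-fold minimum calls fewer entries family sums test fewer sets and fry has another null, by construction.

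Family directions reversed as follows. From day 7 to day 22 with miRNA totals the log2 changes were miR159 -0.41, miR166 -0.78, miR319 -0.72, miR395 -0.74, miR396 -0.40, miR398 -0.38 and miR858 -0.46. With library totals alone they were miR166 -0.44, miR396 -0.0593, miR398 -0.0345 and miR858 -0.12, with RLE factors miR166 -0.34 and miR858 -0.0155, and with mature entries alone miR172 -0.98. From day 22 to day 37 they were miR166 0.21, miR397 0.47 and miR858 0.0336 with miRNA totals, miR166 0.23 with mature entries alone, and miR171 -0.19 with library totals alone and -7.89e-05 with all reads as library size. From day 7 to day 37 they were miR159 -0.36, miR168 -0.16, miR390 -0.0820 and miR394 -0.0186 with library totals alone and miR166 0.79 with mature entries alone. The cause was not tested.

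Ratios of class shares, later to earlier day, moved as follows, for day 22 to 7, 37 to 22 and 37 to 7. Without the 10 most abundant entries known miRNAs had 1.34, 0.741 and 0.995 (1.26, 0.488 and 0.612 with them). The values 1.34 and 0.995 rest on day 7 libraries between which miR396f_1 and miR396e-5p lay far apart. The siRNAs had 0.966, 1.04 and 1.01 (0.945, 0.978, 0.924). Both siRNA ratios of day 37 crossed 1, that to day 22 from libraries that overlapped. The 21-nt siRNAs had 0.981 and 1.27 for the later pairs (0.896, 1.14), and 24-nt siRNAs 0.540 and 0.612 against day 7 (0.487, 0.526). As shares of all reads known miRNAs had 1.88, 0.556 and 1.04, siRNAs 1.41, 1.11 and 1.58, 21-nt siRNAs 1.90, 1.02 and 1.94, 22-nt siRNAs 1.41, 1.16 and 1.64, and 24-nt siRNAs 0.728, 1.23 and 0.896. Of these, known miRNAs 37 to 7, siRNAs 22 to 7 and 37 to 7, 21-nt siRNAs 37 to 22 and 22-nt siRNAs 22 to 7 reversed. The ratios of siRNAs 37 to 22 and 22-nt siRNAs 37 to 7 crossed 1 too. Among reads in small RNA entries they were 0.978 and 0.964, with overlapping libraries. Against day 7, predicted miRNAs had 2.46 and 2.94 and structural RNA 2.20 and 7.86. The ratio of the shares changes with the denominator by construction, since reads in small RNA entries grew from 7.01% to 11.9% of all reads. Depth limits the predicted entries, as a 0 was taken to allow up to 9 reads.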

Other observations

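The entries in this part and the bounds of its tests were chosen only after their values were seen.

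The auxin-linked miR390 and an siRNA that resembles its product were both higher at day 22 than at day 7. The mature entry miR390a-5p went from 37.7 ± 3.05 CPM at day 7 to 391 ± 50.9 at day 22 and 351 ± 63.2 at day 37 (SD, n = 3; day 22 against day 7 log2 3.37, SE 0.17, adjusted p = 1.73e-06), while its hairpin entry went from 179 ± 18.9 over 72.8 ± 12.4 to 19.2 ± 2.96 CPM (log2 -1.30 and then -1.92), so the family sum in the report joins opposite changes. The siRNA novel_sir13900 (CTTTTCTTGACCTTGTAAGACC), which contains most of the sequence of the plant trans-acting siRNA that miR390 releases against auxin response factors, was listed at 0 reads at day 7, 305 to 366 at day 22 and 486 to 503 at day 37. Outside the conserved lists, miR536-3p had 11 to 33 reads at day 7, 6705 to 11376 at day 22 and 3441 to 34903 at day 37, and miR3630-5p, named in the table after sunflower, had means of 38.0, 296 and 264 reads (day 22 against day 7 log2 2.77, adjusted p = 4e-06). The miR6111-5p entry was lower at day 22 than at day 7 (log2 -0.73, adjusted p = 0.0206).

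Some 24-nt siRNAs ran against their class. The siRNA novel_sir15189 (CTCCATTAGGAACTAGCTAGCAAC) had means of 45.0, 3671 and 13684 reads at days 7, 22 and 37, whereas novel_sir1060 (ACTTTGGCCTCGTTTTTTTCCTTG) had 6856, 4678 and 2153. A pair of rising 24-nt entries, novel_sir6998 (ACAAAGTCGGACTAGAGTCAAGCT; 3222, 10915 and 22466 reads) and novel_sir15333 (ACCTCCGACTGAGTCGTTTCCAGG; 1623, 2460 and 12384 reads), are complementary to large-subunit ribosomal RNA sequence. Small nucleolar RNAs, which guide the modification of ribosomal RNA, took 0.0769%, 0.123% and 0.260% of the reads in small RNA entries, and 35 of the 38 that changed were most abundant at day 37. The mean of transfer RNA reads at day 37 depended on a single library, with 13234 in replicate 1 and as few as 1792 in the others. The rise itself did not, as day 7 had 74 to 139 and day 22 had 949 to 1506.

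Other splits of the libraries were counted for the counts of calls below. For all 9 libraries, 1 of 100 splits into 3 groups of 3, the real one, gave as many small RNAs changed over time (6114, the highest other 3249). This argues against a random assignment of these libraries to the days. It cannot decide on differences between plants, since the libraries of a day may be technical. For the pairs of days the 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 87, 61 and 98 miRNAs, 4907, 3533 and 5504 siRNAs and 19, 14 and 18 families for day 22 against 7, 37 against 22 and 37 against 7, each reached by 1 of 10 splits, with 0 as the highest of the others. The same held by length, with 1399, 483 and 1110 21-nt siRNAs higher, 780, 536 and 811 22-nt siRNAs higher and 1568, 734 and 1922 24-nt siRNAs lower, each reached by 1 of 10 splits with 0 as the highest other. The functional lists called were 7, 1 and 5, reached by 4, 8 and 7 of 10 splits, with 8, 3 and 9 as the highest of the others. The number of set calls therefore does not set the real days apart from other groupings of these libraries.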
